A study of Mus musculus with 6 samples.

How the data were processed

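RNA sequencing of thymocytes from C57BL/6 mice was compared between Toxf/f controls and Toxf/fCd4Cre mice, in which Cre recombinase is expressed under Cd4 regulatory sequences, with 3 libraries per group. Per the labels, replicate 1 of both genotypes came from mice aged 4 weeks and replicates 2 and 3 from mice aged 3 weeks. The labels do not state that each replicate is a separate mouse, and they name no batch. Sample titles call the cells double-negative (DN) thymocytes, whereas the labels' protocols name a sort of DN2 cells, and this difference could not be settled from the labels. RNA was extracted with Trizol and libraries were made with a NEBNext Ultra kit, per the labels' protocols.

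For each library, the authors deposited an estimated count and an FPKM value for each of 22298 Ensembl genes, with gene symbols in the same table. Use of fastp 0.18.0, HISAT2 (no version given) and StringTie 1.3.1 was recorded per the submitters' processing notes. The program that made the counts, the genome build and the annotation release are not given in the sources used here, nor is the use of strand in counting, so reads of overlapping and antisense genes may be shared. The deposited estimated counts were not normalized per the file headers, and 9.27% to 9.87% of the values in a library were not whole numbers. The deposited FPKM values carry the authors' scaling for gene length and library size. T cell receptor V segments, Xist and Malat1 are missing from the tables and were not analysed here. Of the 22298 identifiers, 22255 were found in GENCODE M21, which was used only for GC content and transcript length, and no coordinates are given.

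Estimated counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 13934 genes, and libraries were scaled by TMM. The genotype effect, Cd4Cre minus control, was tested with the edgeR quasi-likelihood test, two-sided, with Benjamini-Hochberg (BH) adjustment over the 13934 genes and a threshold of 0.05. All adjusted p-values given for single genes come from this test unless another is named. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F. CPM values are counts scaled to library size by TMM, given as mean ± SD over the 3 libraries of a group. A gene with 0 counts in a group is given as a bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with its 95% interval (Clopper-Pearson, on the share of the counts). Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

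Gene lists for stages of T cell development, cell types that a thymus sample could hold, and cellular pathways (36 lists) were fixed before the data were examined, as were the design, the alternative settings and the rule for named genes. The 30 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2), two-sided, with BH over the 30 lists. The test was repeated with an estimated correlation, and fry was run as a self-contained test. Overrepresentation of each list among higher and among lower genes was tested with a one-sided Fisher's exact test against the 13934 genes, with BH over lists and directions. That test treats genes as independent, so its p-values do not cover correlation between members or variation between libraries. A further 9 lists were written after the values of the most changed genes had been seen and are used only in the closing section.

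The rule for named genes took the 12 highest and 12 lowest log2 fold changes among genes past the threshold with a group mean of at least 2 CPM and no overlap between groups, leaving out Gm and Rik names and pseudogenes. It also took the Tox family and fixed stage and survival genes (Kit, Cd44, Il2ra, Ptcra, Rag1, Cd4, Cd8a, Cd8b1, Trac, Trdc, Tcf7, Gata3, Bcl11b, Notch1, Id2, Id3, Bcl2, Bcl2l1 and Bcl2l11), up to 4 members with the smallest p per list, and the 5 genes with the smallest p. It covers 151 genes. Any other gene is marked in the text as chosen after its values were seen. Results of a few genes that the rule or the lists include are not reported here.

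Library totals of estimated counts ranged from 14550593 to 16099023. On simulated counts for these 13934 genes (5 runs of 200 changed genes, same group sizes), the test recovered 56.1% of genes changed 1.5-fold, 80% of those changed 2-fold and 96.7% of those changed 4-fold. Of 832 calls in the simulations, 57 were false (6.9%). In 1 separate run with 20 changed genes, camera called 0 of 30 unchanged lists. Simulated genes were drawn independently of each other, so this run could not show false list calls that come from correlated members.

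Alternative settings fixed at that point were no filter, a mean of at least 5 CPM, DESeq2 size factors, quantile normalization, DESeq2 1.42.0 as the test, limma with array weights, the replicate number as a block, age as a covariate, removal of T cell receptor and immunoglobulin genes, a 2-fold minimum, pseudocounts of 0.1 and 0.01 on FPKM, and leaving out each library. Chosen after seeing the data were limma on FPKM with a pseudocount of 1 and the 3-week libraries alone. So was a per-library correction for GC content and transcript length, followed by limma, for which 13927 of 13934 genes had a value. Planned transcript-level alternatives were not run because the tables hold genes only. Genes of families with near-identical members (immunoglobulin segments and constant regions, Trgc and Trbc genes, Klra receptors, globins, H2 class I, ribosomal proteins) share reads, so values of single members are uncertain.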

Results

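Transcript levels were measured by RNA sequencing in 3 Toxf/f control libraries and 3 Toxf/fCd4Cre libraries that the sample titles call double-negative thymocytes, although transcripts of later thymocytes and of epithelium were abundant in them (Cd8a at 1710 and Krt18 at 339 CPM in the controls). Double-negative thymocytes are the early T cell precursors that carry neither CD4 nor CD8 on their surface, and Tox encodes a nuclear HMG-box protein needed for development of CD4 T cells. The controls held 15383391, 14550593 and 15146238 estimated counts (replicates 1 to 3), and the Cd4Cre libraries held 15758438, 16099023 and 14579898. The 50 most abundant genes took 11.4% to 12.2% of the counts of a library. Genotype separated the libraries on the first principal component of the 500 most variable genes (53.7% of the variance), where controls lay between 15.1 and 17.9 and Cd4Cre libraries between -19.1 and -14. The next components (19.1% and 11.6% of the variance) did not separate the genotypes. Spearman correlations across genes, which are not independent replicates, were 0.9895 to 0.9962 within groups and 0.9863 to 0.9906 between them.

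Tox (ENSMUSG00000041272), the targeted gene, was measured first as a check of the labels. Its level was 109, 99.2 and 103 CPM in the controls and 12.5, 15.1 and 10.2 CPM in the Cd4Cre libraries. The mean fell from 104 ± 4.89 to 12.6 ± 2.43 CPM (SD, n = 3), a log2 fold change of -3.03 (SE 0.12, edgeR quasi-likelihood adjusted p = 3.55e-08), which left 12.2% of the control level. The deposited FPKM values were 26.3 ± 1.35 and 3.17 ± 0.62. A two-sided exact permutation test of the log2 CPM values gave p = 0.1, the smallest that 3 against 3 libraries allow. The counts cover the whole gene, so reads from exons outside the deleted part are included. The related genes Tox2, Tox3 and Tox4 did not pass the test, with log2 fold changes of -0.05, 0.10 and -0.02.

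The comparison of the genotypes asks which transcripts differ between the Toxf/fCd4Cre and the Toxf/f libraries. No library came from mice with Cd4Cre and an intact Tox gene, so effects of Tox loss and of Cre itself cannot be told apart. In the Cd4Cre libraries, 17 of 26 mature T cell genes (1 rose), 18 of 30 type I interferon response genes and 16 of 20 immunoglobulin genes fell, whereas 9 of 17 gamma-delta T cell genes (2 fell) and 5 of 19 NK, NKT and cytotoxic cell genes rose. Of these 5 list calls only that of the immunoglobulin genes held with an estimated correlation, where the NK list had an adjusted p = 0.43 and the other 3 lists 0.10 to 0.12. Itm2a, which encodes a membrane protein of activated thymocytes, fell from 297 ± 6.22 to 75 ± 2.58 CPM (n = 3, log2 fold change -1.98, SE 0.07). Cd163l1, a scavenger receptor family gene of gamma-delta T cells, rose from 2.63 ± 0.207 to 48.1 ± 7.59 CPM (log2 fold change 4.19, SE 0.15). Of 13934 genes tested, 572 passed adjusted p 0.05 in the edgeR quasi-likelihood test, 160 higher and 412 lower in Cd4Cre, and 2276 had an unadjusted p under 0.05. The median size of the log2 change was 0.64 among higher and 0.85 among lower genes, and 42 higher and 163 lower genes changed at least 2-fold. All 572 had no overlap between the groups, a condition that 10% of unselected genes meet by chance. These genes were selected on the same values, so the lack of overlap is no separate support. By limma, rather than edgeR, after a correction for GC content and length, 856 genes passed, 369 higher and 487 lower. Of these, 549 were among the 572. The count was 3570 with array weights, 311 and 280 without control replicate 1 or 2, 326 and 1308 without Cd4Cre replicate 1 or 3, and 151 in the 3-week libraries alone. Control replicate 2 was the only library with more than 5 counts of Y-linked genes.

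**Figure D1:**
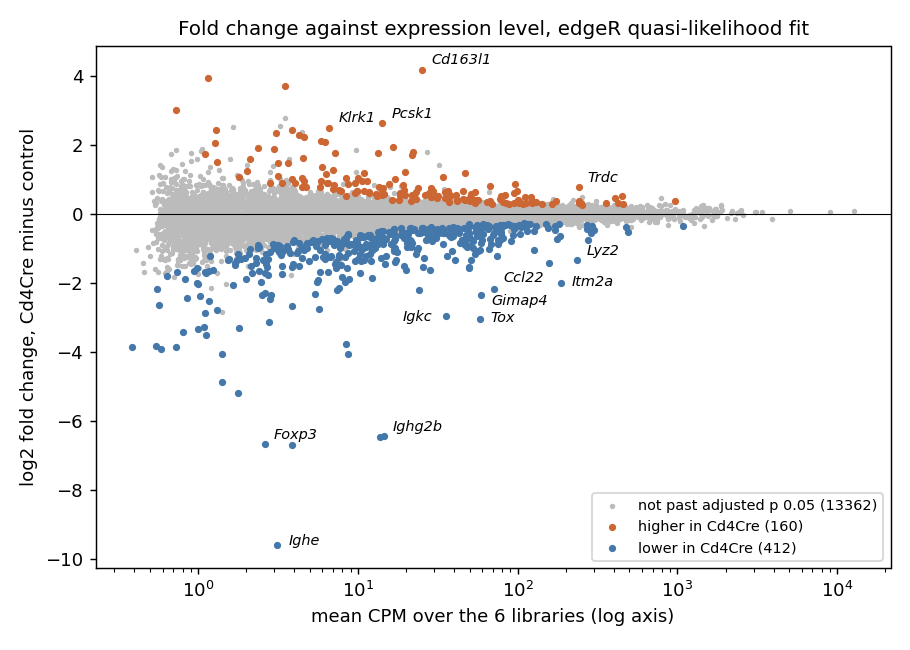
Log2 fold change, Cd4Cre minus control, of each of the 13934 genes tested against its mean CPM over the 6 libraries on a log axis, with genes past adjusted p 0.05 in colour (160 higher, 412 lower). The fitted value of Ighe, with 0 counts in the Cd4Cre group, has no finite estimate and its position depends on the prior count.

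The 12 highest genes held 5 natural killer receptor genes: Klra5 (log2 fold change 3.95), Klrk1 (2.51), Klra1 (2.43), Klrb1b (2.25) and Klrb1c (2.10). Klrk1, which encodes the activating receptor NKG2D, rose from 1.97 ± 0.16 to 11.2 ± 2.77 CPM (n = 3). Pcsk1, a prohormone-cleaving protease of endocrine cells, rose from 3.93 ± 0.275 to 24.4 ± 3.06 CPM, and Chad, a cartilage matrix protein gene, from 0.488 ± 0.21 to 6.51 ± 2.15 CPM. B4galnt4, a glycosyltransferase gene, Krt6a, a keratin of stratified epithelium, Fam20a and Tns4 had log2 fold changes of 2.43, 2.36, 2.30 and 2.12. Together with Cd163l1 these make up the 12, with adjusted p from 3.13e-08 to 0.0031 (edgeR quasi-likelihood).

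The 12 lowest genes were mostly genes of immunoglobulin chains. Ighe had 284 counts in the controls and 0 in the Cd4Cre group, at least 96.7-fold lower against a floor of 3 counts over the group. Ighg2c had 345 and 3 counts, a ratio of 0.851% (95% interval 0.175% to 2.51%). Igha fell from 27.2 ± 4 to 0.299 ± 0.173 CPM and Ighg2b from 28.8 ± 3.24 to 0.328 ± 0.0846 CPM (n = 3). Ighg1, Igkv1-117, Jchain, which encodes the joining chain of antibody polymers, and Igkv10-96 had log2 fold changes of -4.86, -4.07, -4.05 and -3.51. Genes outside these loci included Foxp3, the regulatory T cell factor, with 236 and 2 counts (ratio 0.829%, 95% interval 0.0998% to 3.03%), Pla2g2d, a secreted phospholipase of dendritic cells (15.7 ± 1.12 to 1.15 ± 0.233 CPM), and Fcrl5, an Fc receptor-like gene of B cells (-3.30). The 5 smallest p overall were those of Ighg2b, Igkc, Itm2a, Cd163l1 and Igha.

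Among genes of mature single-positive and recirculating T cells, 17 of 26 fell, 1 rose and 8 did not pass. The GTPase genes Gimap4 and Gimap3, which act in lymphocyte survival, fell from 98.2 ± 7.52 to 19.5 ± 3.72 CPM and from 39.9 ± 1.68 to 8.62 ± 1.49 CPM (n = 3). Ccr7, the receptor that draws thymocytes to the medulla, fell from 73.3 ± 8.48 to 29.1 ± 3.63 CPM. Chosen after their values were seen, S1pr1, the receptor for thymus exit, and Klf2, the factor that induces it, fell by 1.14 and 0.96 on the log2 scale, and Icos rose by 0.52 (not past the threshold without any 1 of the controls or Cd4Cre replicate 1). The list's median log2 fold change was -0.51 and its camera adjusted p 9.9e-20 (adjusted p = 0.10 with an estimated correlation), and 19 members were lower and 1 higher adjusted over the list alone. Lower genes held more of its members than independent draws of genes would give (one-sided Fisher's exact test, adjusted p = 3.6e-19).

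Of 30 type I interferon response genes, 18 fell and 12 did not pass. Oas2, a sensor of double-stranded RNA, fell from 13.8 ± 0.6 to 3.78 ± 0.398 CPM (n = 3), and Zbp1, a nucleic acid sensor, from 65 ± 4.98 to 34 ± 2.36 CPM. Ifi27l2a and Oas3 had log2 fold changes of -1.57 and -0.97. The factor Irf7, chosen after its values were seen, had a change of -0.74. The list's median was -0.46 (camera adjusted p = 7.1e-22, adjusted p = 0.12 with an estimated correlation), with 22 lower and 1 higher adjusted over the list alone and overrepresentation among lower genes (Fisher's exact test, adjusted p = 3.6e-19).

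Immunoglobulin genes had 20 tested members of 247 listed, of which 16 fell and 4 did not pass. The kappa light chain constant gene Igkc fell from 63.1 ± 3.3 to 8.12 ± 0.264 CPM (n = 3) and the lambda gene Iglc2 from 4.78 ± 1.13 to 0.93 ± 0.0229 CPM. Chosen after its values were seen, Ighm, the constant gene of unswitched IgM, was 534 ± 9.63 and 610 ± 41 CPM and did not pass. Its name prefix also put Ighmbp2, which is not an antibody gene, on the list. The median was -3.31 (camera adjusted p = 4.6e-21), with 17 lower and 2 higher adjusted over the list alone, and lower genes were enriched for the list (Fisher's exact test, adjusted p = 6.7e-20). This was the 1 list whose call held with an estimated correlation (adjusted p = 0.013). Of 17 B cell markers, 4 fell and 13 did not pass, the former including Fcer2a, the low-affinity IgE receptor (log2 fold change -2.75), Ms4a1 (-1.67) and Blnk (-0.68, not past the threshold without control replicate 1 or 2 or Cd4Cre replicate 1). Cd79a, chosen after its values were seen, was 16.2 ± 3.14 and 8.09 ± 4.38 CPM and did not pass. The B cell list's median was -0.26 (camera adjusted p = 5.2e-06, adjusted p = 0.35 with an estimated correlation), with 8 lower and 1 higher adjusted over the list alone, and its Fisher's exact test among lower genes gave an adjusted p of 0.0079.

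**Figure D2:**
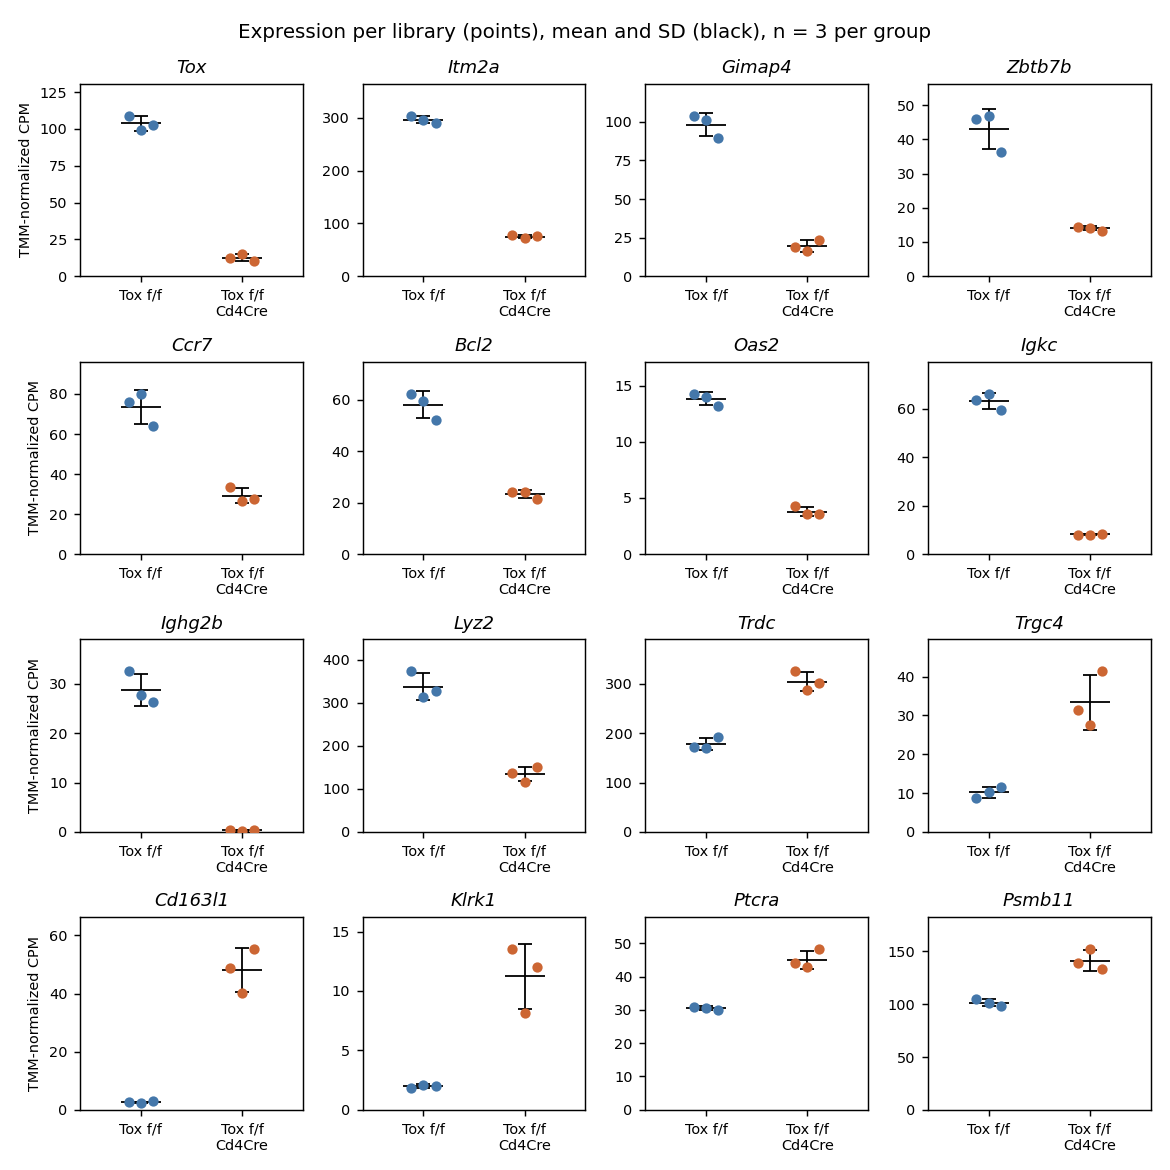
TMM-scaled CPM of 16 named genes in each library (points), with the mean and SD of each group in black (n = 3). In each of the 16 genes the 3 libraries of one genotype lie above all 3 of the other, for example Tox at 99.2 to 109 CPM in controls against 10.2 to 15.1 CPM in Cd4Cre.

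Gamma-delta T cell genes moved the other way, with 9 of 17 higher, 2 lower and 6 not past the threshold. Trdc, the delta chain constant gene, rose from 178 ± 12.4 to 305 ± 18.8 CPM (n = 3) and the gamma chain gene Trgc4 from 10.2 ± 1.42 to 33.3 ± 7.17 CPM. Ccr6, the chemokine receptor of interleukin-17-producing cells, and Rora fell by 2.46 and 0.61 on the log2 scale, the latter not past the threshold without any 1 of the controls or Cd4Cre replicate 1 or 2. Chosen after their values were seen, Maf and Blk rose by 0.75 and 1.05, and Sox13, a factor of gamma-delta cells, was 14.5 and 14.6 CPM. The median was 0.52 (camera adjusted p = 1.6e-08, adjusted p = 0.12 with an estimated correlation), with 11 higher and 3 lower adjusted over the list alone, and higher genes were enriched for the list (Fisher's exact test, adjusted p = 9.3e-13). Among NK, NKT and cytotoxic cell genes, 5 of 19 rose and 14 did not pass, including Gzmb, a killing protease (3.34 ± 1.21 to 8.53 ± 1.46 CPM). Their median was 0.25 (camera adjusted p = 0.026, adjusted p = 0.43 with an estimated correlation), 6 were higher and 1 lower adjusted over the list alone, and the Fisher's exact test among higher genes gave an adjusted p of 1.9e-05. The camera call of this list was lost without control replicate 3 or Cd4Cre replicate 1 or 3.

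T cell receptor signalling response genes held 8 lower, 1 higher and 15 not past the threshold of 24. Nr4a1, an early gene of receptor signalling, fell from 88.3 ± 6.42 to 43.5 ± 3.44 CPM (n = 3), and Cd69, an activation marker of selected thymocytes, from 69.3 ± 8.81 to 35.2 ± 3.87 CPM. Nr4a3 and Tnfrsf18 had log2 fold changes of -0.80 and -0.75. The list's median was -0.13 (camera adjusted p = 0.0035, lost without Cd4Cre replicate 3, adjusted p = 0.58 with an estimated correlation), with 11 lower and 4 higher adjusted over the list alone, and its Fisher's exact test among lower genes gave an adjusted p of 3.2e-06. Of 18 inhibitory receptor and exhaustion-associated genes, 4 fell and 14 did not pass. Besides Nr4a3 these were Tnfrsf9 (-1.72), the checkpoint receptor gene Pdcd1 (16.5 ± 0.117 to 7.36 ± 1.3 CPM) and Btla (-0.83). Their median was -0.24 (camera adjusted p = 0.0039, adjusted p = 0.30 with an estimated correlation), with 5 lower adjusted over the list alone and a Fisher's exact test adjusted p of 0.009 among lower genes.

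Among regulators of T cell fate and survival, Zbtb7b (ThPOK), the factor that directs the CD4 lineage, fell from 43 ± 5.85 to 14 ± 0.582 CPM (n = 3, log2 fold change -1.62, SE 0.11). Bcl2, which protects from apoptosis, fell from 57.9 ± 5.21 to 23.2 ± 1.56 CPM (-1.32, SE 0.09), while Bcl2l1 was 208 and 200 CPM and did not pass. Bcl2l11 and Birc3, which act in cell death, had smaller changes of -0.34 and -0.29. Of 23 T lineage transcription factors, Zbtb7b and Lef1 (-0.47) fell, Gfi1 (0.34) rose and 20 did not pass, and the list had no direction (camera adjusted p = 0.55, median 0.07, mean -0.04, 4 higher and 3 lower adjusted over the list alone). Tcf7 (3040 and 3160 CPM), Gata3, Bcl11b, Notch1, Id2 and Id3 did not pass, with log2 fold changes of 0.06, 0.08, -0.16, 0.01, -0.42 and 0.28. Apoptosis regulators had 3 lower and 27 not past the threshold of 30 (median -0.06, camera adjusted p = 0.015, adjusted p = 0.30 with an estimated correlation, 4 lower adjusted over the list alone, Fisher's exact test adjusted p = 0.23 among lower genes), a call lost without Cd4Cre replicate 2. Leaving out 1 of several libraries ended the calls of Lef1, Gfi1, Bcl2l11 and Birc3, among them control replicate 2 for all 4 genes.

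Few stage markers of thymocyte development passed the test, and the labels name both DN and DN2 cells. Ptcra, the pre-T cell receptor alpha chain of DN3 cells, rose from 30.6 ± 0.513 to 45 ± 2.86 CPM (n = 3, log2 fold change 0.56, SE 0.08). Kit and Cd44, which mark DN2 cells, were 20.4 and 42.7 CPM in controls and 14.5 and 36.7 CPM in Cd4Cre, and Il2ra was 96.4 and 110 CPM, none past the threshold. In controls, transcripts of the later coreceptors were abundant, with Cd8a at 1710 ± 49.3, Cd8b1 at 1240 ± 30.2 and Cd4 at 918 ± 11.2 CPM, and Rag1 stood at 4930 ± 148 CPM. In Cd4Cre these were 2030, 1390, 941 and 5240 CPM, and neither they nor Trac (366 and 409 CPM) passed. Of 21 DN3 and pre-T cell receptor stage genes, Ptcra and Notch3 (0.56) rose and 19 did not pass (median 0.10, camera adjusted p = 0.0078, adjusted p = 0.17 with an estimated correlation, 2 higher adjusted over the list alone, Fisher's exact test adjusted p = 0.11 among higher genes). Early progenitor and DN1-DN2 genes had 1 lower, Mef2c (-1.24), and 18 not past the threshold of 19 (median -0.10, camera adjusted p = 0.026, adjusted p = 0.30 with an estimated correlation, 5 lower adjusted over the list alone, Fisher's exact test adjusted p = 1 among lower genes). Of 22 genes of the DN4, ISP and DP stages, Aqp11 (0.27) rose, Cd2 (-0.34) fell and 20 did not pass (median 0.05, camera adjusted p = 0.03, adjusted p = 0.30 with an estimated correlation, 6 higher and 1 lower adjusted over the list alone, Fisher's exact test adjusted p = 0.66 among higher genes). Of 18 Notch target genes, Ptcra, Notch3 and Myc (0.32) rose, Lfng (-0.62) fell and 14 did not pass (median 0.07, camera adjusted p = 0.047, adjusted p = 0.58 with an estimated correlation, 4 higher and 1 lower adjusted over the list alone, Fisher's exact test adjusted p = 0.0071 among higher genes). Calls of Notch3, Myc, Aqp11 and Cd2 ended without control replicate 1 or 2, among others, the early progenitor call without Cd4Cre replicate 3, the Notch call without control replicate 1 or 3 or Cd4Cre replicate 2 or with the GC and length correction (adjusted p = 0.052), and the DN4 to DP call without control replicate 3 or Cd4Cre replicate 2 or 3.

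Markers of other thymic cells were present in both genotypes and moved in both directions. Of 21 thymic epithelial and stromal markers, 5 rose, 1 fell and 15 did not pass. Psmb11, the proteasome subunit of cortical epithelium, rose from 101 ± 2.98 to 141 ± 9.8 CPM (n = 3), the keratin gene Krt18 from 339 ± 20.5 to 470 ± 22 CPM, and Cxcl12 and Krt5 by 0.39 and 0.44 on the log2 scale. Krt8 (0.31) and Krt14 (-0.63), named after their values were seen, complete these 6 genes, and the calls of Krt8, Krt14, Krt5 and Cxcl12 ended without control replicate 2, among others. The stromal list had no camera call (adjusted p = 0.11, or 0.023 without Cd4Cre replicate 3, median 0.13, 8 higher and 4 lower adjusted over the list alone) but was enriched among higher genes (Fisher's exact test, adjusted p = 2.8e-05). Of 26 conventional dendritic cell and macrophage markers, Lyz2, a lysozyme gene (338 ± 31 to 134 ± 16.7 CPM), Lyz1 (-0.95) and Ctss (-0.58) fell and 23 did not pass. That list had no direction (camera adjusted p = 0.63, median 0.04, mean -0.04, test down, 4 higher and 3 lower adjusted over the list alone). Of 17 plasmacytoid dendritic cell markers, Cybb (-0.67, or -0.39 and not past the threshold on FPKM with a pseudocount of 0.1) and Pacsin1 (-0.78, not past the threshold without control replicate 1 or 2) fell and 15 did not pass (median -0.24, camera adjusted p = 0.0012, adjusted p = 0.35 with an estimated correlation, 6 lower adjusted over the list alone, Fisher's exact test adjusted p = 0.31 among lower genes).

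Among 17 neutrophil and monocyte markers, the monocyte chemokine receptor gene Ccr2 (6.81 ± 1.87 to 26.5 ± 9.82 CPM, n = 3), Ltf (1.02) and Lcn2 (0.72) rose and 14 did not pass. Ltf and Lcn2 encode secreted antimicrobial proteins that epithelia also make, and Lcn2 did not pass without control replicate 2 or 3 or Cd4Cre replicate 1. The list's median was 0.23 (camera adjusted p = 0.026, lost without control replicate 3 or Cd4Cre replicate 1, adjusted p = 0.52 with an estimated correlation, 3 higher adjusted over the list alone, Fisher's exact test adjusted p = 0.0067 among higher genes). Of 13 innate lymphoid cell markers, Cxcr5 (-1.74), Rora and Ltb (-0.30) fell, Cxcr6 (1.26) rose and 9 did not pass (median -0.42, camera adjusted p = 0.0099, lost without Cd4Cre replicate 2, adjusted p = 0.36 with an estimated correlation, 7 lower and 2 higher adjusted over the list alone, Fisher's exact test adjusted p = 0.029 among lower genes). Without control replicate 1, among others, Ltb and Cxcr6 did not pass. Of 10 erythroid markers, edgeR called 0, with 1 at an unadjusted p under 0.05, and DESeq2 called 0. Their level varied between libraries, with Hbb-bs at 659 ± 504 and 913 ± 555 CPM, and their camera adjusted p of 0.58 became 0.015, up, without control replicate 3.

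**Figure D3:**
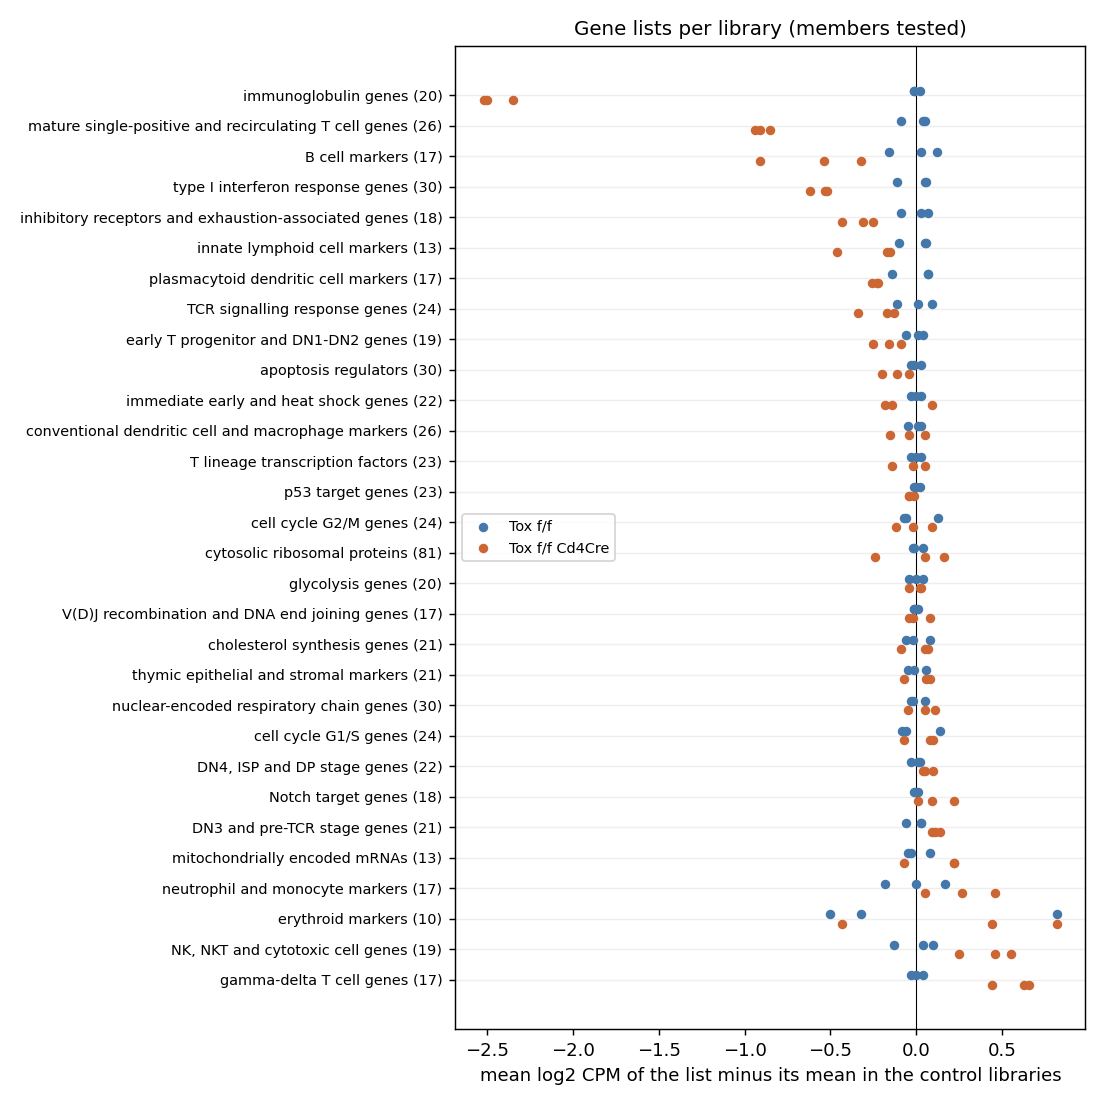
Mean log2 CPM of each tested list in each library minus its mean in the control libraries, with the number of tested members in brackets. Points of both genotypes stand apart by at least 0.41 for the mature T cell and interferon lists, while many other lists lie near 0 in both.

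Lists of general cell functions held few genes called by edgeR. The 13 mitochondrially encoded mRNAs had 0 past the threshold by edgeR, 0 by DESeq2 and 0 at an unadjusted p under 0.05, but 3 by limma after the GC and length correction, with mt-Co1 at 12400 ± 740 and 13300 ± 745 CPM (n = 3). Their camera call (median 0.13, adjusted p = 0.03, adjusted p = 0.64 with an estimated correlation, Fisher's exact test adjusted p = 1 among higher genes) was lost without control replicate 1 or 3 or Cd4Cre replicate 2 or 3, and was 0.00011 after the GC and length correction. V(D)J recombination and end joining genes had 1 lower of 17, Atm (-0.35, not past the threshold without any 1 of the controls or Cd4Cre replicate 1 or 2), and 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.92). No member passed edgeR, over all genes or adjusted over the list alone, in 8 further lists, and the number of members, the number at an unadjusted p under 0.05 and the camera adjusted p are given in that order. These were G1/S genes (24 members, 0 unadjusted, camera adjusted p = 0.21), G2/M genes (24, 2, 0.92), p53 targets (23, 4, 0.89) and respiratory chain genes (30, 3, 0.14). The others were glycolysis (20, 1, 0.58), cholesterol synthesis (21, 2, 0.58), ribosomal protein (81, 1, 0.80) and immediate early and heat shock genes (22, 2, 0.16). DESeq2 called 1 immediate early gene and 0 in the other 7 lists, limma after the GC and length correction called 3 ribosomal protein, 1 p53 and 1 immediate early gene, and limma with array weights called 4 to 11 genes in each of the 8 lists. The camera direction was down while the median was 0.01 for the G2/M, p53 and V(D)J lists (means -0.01, -0.03 and 0.01), and up while the mean was -0.04 for the T lineage factors.

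Single libraries and the GC and length correction moved several of these lists. Without Cd4Cre replicate 2, camera called the ribosomal proteins up (adjusted p = 9.7e-09), the G1/S genes up (0.0074), the respiratory chain genes up (0.0041) and the immediate early genes down (0.0075), and without Cd4Cre replicate 3 the ribosomal proteins down (0.023). Without control replicate 3, G1/S (0.0012) and respiratory chain genes (0.029) were called up. After the GC and length correction, respiratory chain genes were called up (0.01) and immediate early genes down (0.017). With the preset correlation, camera called 17 of 30 lists, 7 up and 10 down, and with an estimated correlation 1, the immunoglobulin list. Correlation between members does not alone account for this loss. The DN3 list had an estimated correlation of -0.021, yet its camera adjusted p went from 0.0078 to 0.17. The fry test, which asks whether a list's genes move on balance one way without comparing them with other genes, passed for 7 lists: immunoglobulin, mature T cell, gamma-delta, interferon, DN3, inhibitory receptor and B cell genes (adjusted p from 2.9e-05 to 0.049).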

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

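The tests in this part were chosen after the results were seen, except that leaving out each library was fixed before the data were examined. Control replicate 2 held a summed count of 3740 for the 4 Y-linked genes in the tables, Ddx3y (1280), Uty (438), Kdm5d (1427) and Eif2s3y (595), while the other 5 libraries held 2 to 5. These genes were outside the main measurement, since the filter on counts removed them, and the labels give no sex. That library therefore held RNA of male cells and the other 5 held next to none, so sex differs within the control group. Without that library 280 genes passed the threshold, of which 278 were among the 572.

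The first pattern is the presence of transcripts of other thymic cells in libraries titled double-negative, which come from sorted cells per the labels' protocols. Of 21 tested epithelial and stromal markers fixed before the data were examined, 20 had a control mean of at least 10 CPM (median 67.6 CPM). Among them were Krt18 (339 CPM) and, chosen after its values were seen, Ccl25 (628 CPM). Such cells or their RNA may have entered the libraries of both groups, although a sort for thymocytes would remove them. The count restates the pattern, with a minimum set after the values were seen, so it does not test that entry. A different share of thymocytes, as the only difference between the groups, would move the markers of all other cells alike. That is argued against by 8 higher and 10 lower called genes among 108 members of 6 lists of other cells. A different share along with changes in some of the other cell types stays open. The control levels go with entry of double-positive thymocytes, since Cd8a stood at 56 times the level of Ptcra. Cd8b1 (1240 CPM), Cd4 (918 CPM) and Rag1 (4930 CPM) also stood far above the DN2 markers Kit (20.4 CPM) and Cd44 (42.7 CPM). The fall of Tox to 12.2% of the control level also goes with cells in which the Cd4 sequences driving Cre had been active. Together these values argue against libraries of DN2 cells alone. No library of known purity was there to compare with, so whether double-positive or late double-negative cells gave these transcripts was not decided. For this question no biological explanation was tested.

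The second pattern is the fall of mature T cell and type I interferon response genes. GC content and transcript length as the whole cause are argued against. Of the 35 members called lower (of 56), 34 were still called lower by limma after correction. Medians were -0.46 before and -0.43 after for the interferon list, and -0.51 and -0.54 for the mature T cell list. A single library of either group is argued against by the gap of at least 0.41 between the lowest control and the highest Cd4Cre mean log2 CPM of a list, against a largest range of 0.17 within a group. Fewer mature thymocytes in the Cd4Cre libraries, which the genotype could bring about, and fewer transcripts per cell cannot be told apart in bulk RNA: 8 of 26 mature T cell genes did not pass, and the level of each in the other cells is unknown. Both remain hypotheses.

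The third pattern is the fall of immunoglobulin genes. Fewer B cells of every kind as the whole cause are argued against: 10 B lineage markers had a median log2 fold change of -0.84 (lower quartile -1.5), against -6.44 for 6 class-switched heavy chain genes (upper quartile -5.25, Ighe at its bound) and an upper quartile of -2.57 over all 20 immunoglobulin genes. Reads moved between light chain paralogs are argued against by the summed light chain counts of 118 genes, which fell to 13.3% of the control level (104 ± 4.98 to 13.8 ± 0.245 CPM). Reads moved between heavy chain paralogs would leave the light chain sum unchanged, so its fall argues against them as the whole cause. For the heavy chain genes such moves stay open: the summed counts of 144 heavy chain genes were 98.5% of the control level (623 ± 16.8 and 613 ± 44.9 CPM), but Ighm made up 86% of the control sum and the 6 class-switched genes 12%, so the sum could not have fallen far with them. Fewer class-switched B cells or plasma cells in the Cd4Cre libraries may be a candidate source, from sort carry-over or from the thymus itself, and no test here tells these sources apart. Of 15 class switch and plasma cell genes, listed after values were seen, 10 were lower, among them Jchain (-4.05). Sdc1 was higher (0.56), and Xbp1, Mzb1, Prdm1 and Cd38 did not pass (0.22, 0.41, 0.16 and 0.04 on the log2 scale).

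The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Every split but the real one mixes the genotypes within its groups, so its counts are not a baseline without a genotype effect. As many genes as the real split (572) came from 1 of 10 splits, the real one, and the highest other split gave 6. As many lists (17) came from 1 of 10 splits as well, and the highest other gave 16, the lowest 4.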

How the results depend on the processing

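Tox kept its direction and passed the threshold in all 21 alternatives with a value for it, with log2 fold changes from -3.18 to -2.72. The 572 genes (160 higher, 412 lower) became 3570 with array weights (1584 and 1986, 572 shared), 205 with a 2-fold minimum (42 and 163, with 7 lists overrepresented rather than 12) and 280 to 1308 without 1 library (63 to 502 higher, 217 to 806 lower). The 3-week libraries alone, chosen after seeing the data, gave 151 (28 and 123, 150 shared). By limma rather than edgeR, higher genes numbered 98, 95 and 95 on FPKM with pseudocounts of 1, 0.1 and 0.01. After the GC and length correction, also by limma, 369 were higher and 487 lower. In these settings the test changed along with the values. The pseudocount of 1 and the correction were chosen after seeing the data. No gene shared with the 572 had the opposite direction in any alternative. The causes were not tested. All other totals lay between 389 and 856.

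The values showed no pairing of libraries by replicate number, although same-numbered libraries share an age per the labels. Deviations of same-numbered libraries correlated at 0.08, -0.11 and -0.04, and 2 of 6 libraries correlated best with their own number. With the replicate number as a block 440 genes passed (122 higher, 318 lower, 425 shared) and 17 lists were called. Age as a covariate gave 463 genes (127 higher, 336 lower, 456 shared). Of 110 named calls, the block ended 10 and the age covariate 7 (Bcl2l11, Aqp11, Birc3, Cxcr6, Rora, Ltb and Krt8). Lists called by camera numbered 14 to 18 in all settings but the estimated correlation, where it was 1.

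Of 110 named genes past the threshold, 0 reversed, 51 passed in every alternative, 58 in all but the 2-fold minimum and 80 in all but that and the 3-week libraries. Of 83 others, 54 passed in some alternative. All reversals were in genes and lists that had not passed, and 1 of them then passed, the ribosomal proteins without Cd4Cre replicate 3 (down, 0.023). Log2 fold changes were 0 for Notch1 with a mean of 5 CPM and on FPKM (3 pseudocounts). With quantile normalization they were 0.08 (Tox2), -0.01 (Tcf7), -0.01 (Notch1) and 0 (mt-Co1), and with array weights 0.18 (Tox2). On FPKM Tox3 gave -0.06, -0.09 and -0.09. After the GC and length correction they were 0.04 (Tox4) and -0.03 (Sox13), and in the 3-week libraries -0.01 (Notch1), -0.12 (Sox13) and -0.07 (Tnfsf11). Without 1 library they ranged from -0.2 to 0.11 (Tox2), -0.03 to 0.21 (Tox3), -0.03 to 0.01 (Tox4), -0.01 to 0.08 (Cd4), 0 to 0.12 (Tcf7), -0.03 to 0.19 (Gata3), -0.07 to 0.1 (Notch1), -0.12 to 0.08 (Sox13), -0.11 to 0.31 (Tnfsf11), -0.09 to 1.31 (Hbb-bs) and -0.01 to 0.29 (mt-Nd3).

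Camera adjusted p of lists that turned were, without a filter, 0.99 (p53 targets) and 0.96 (G2/M), after the GC and length correction 0.83 (G2/M) and 0.55 (V(D)J), and in the 3-week libraries 1 (G1/S), 0.97 (V(D)J), 0.98 (cholesterol), 0.33 (ribosomal) and 0.98 (erythroid). Without 1 library they ranged from 0.63 to 1 (p53), 0.078 to 0.95 (G2/M), 0.33 to 0.97 (V(D)J), 9.7e-09 to 0.95 (ribosomal), 0.13 to 0.95 (glycolysis), 0.09 to 0.95 (cholesterol), 0.015 to 0.95 (erythroid), 0.068 to 0.79 (T lineage factors) and 0.22 to 0.95 (dendritic cells and macrophages). At this depth and n, simulated 1.5-fold changes were recovered in 56.1% of genes.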

Other observations

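The gene lists and tests in this part were chosen after the results were seen, except for the lists named as fixed, and so are not independent evidence of their direction. Of 17 genes of cortical thymic epithelium, 7 were higher and 10 did not pass, the former including Prss16, a protease that prepares peptides for selection (844 ± 35.1 to 1100 ± 83 CPM, n = 3), and Pax1 (92.9 to 130 CPM), neither past the threshold without control replicate 1, 2 or 3 or Cd4Cre replicate 1. Genes of medullary epithelium and its maturation had 10 lower, 1 higher (Krt5) and 9 not past the threshold of 20, including the chemokine gene Ccl21a (225 ± 23.8 to 144 ± 18.9 CPM), Cd40 (-0.86), Cd80 (-0.95) and Fezf2 (-0.52, not past the threshold without any 1 of the controls or Cd4Cre replicate 2). Genes of mimetic epithelial cells, which take on features of other tissues, had 8 higher, 1 lower (Dclk1) and 12 not past the threshold of 21 (median 0.15), including Pcsk1 and the airway gene Bpifa1 (6.03 ± 0.941 to 20.7 ± 3.02 CPM). Genes of mature dendritic cells and medullary chemokines had 10 lower of 15, with Ccl22 falling from 117 ± 14.8 to 25.9 ± 3.22 CPM. The medullary and dendritic lists share Cd40, Cd80, Cd86, Ccl19 and Relb, of which 4 were among the lower genes of both, so their falls are not separate evidence, and 6 of the 15 other medullary genes were lower and 1 higher. Whether dendritic cells also express some of those 15 genes was not tested. With an estimated correlation, camera gave these 4 lists adjusted p of 0.054, 0.046, 0.033 and 0.028, so the call of the cortical list was lost, and 8, 3, 3 and 1 of their members were also on lists fixed before the data were examined.

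Among lymphocyte genes, 6 of 10 Klr family receptors were higher (median 2.17) and 5 of 8 Gimap genes lower (median -0.50), with adjusted p of 0.049 and 0.043 with an estimated correlation. CD4 lineage and helper genes had 9 lower and 1 higher of 13 (median -1.44, adjusted p = 0.046 with an estimated correlation), including the CD40 ligand gene Cd40lg (8.96 ± 0.824 to 2.37 ± 0.377 CPM, n = 3), Tnfrsf4 (-1.97) and the helper cytokine gene Il21 (-3.86). Class switch and plasma cell genes had 10 lower and 1 higher (Sdc1) of 15 (median -3.34, with Ighe at its bound too, adjusted p = 0.014 with an estimated correlation), and B lineage markers had 4 lower of 10 (median -0.84, adjusted p = 0.046 with an estimated correlation). All 9 lists passed camera with the preset correlation (adjusted p from 9.4e-14 to 4.4e-05), and 8 did with an estimated one, all but the cortical list. Of the tested members, 11 of 13 CD4 lineage, 6 of 15 class switch, 4 of 10 Klr, 3 of 8 Gimap and all 10 B lineage genes were also on the fixed lists, so these lists are not separate results.

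The cause of the medullary change was not decided by the tests here. A lower share of every medullary epithelial cell stays open, as do fewer mature dendritic cells for the genes on both lists. The 8 mimetic genes called higher decide nothing here, since that list was written after the most changed genes had been seen and holds 2 of the 12 highest, Pcsk1 and Krt6a, and Ltf and Lcn2 are also neutrophil and monocyte markers. The level of Cd40lg, which encodes a signal for medullary epithelium, had a log2 fold change of -1.91, as fewer CD4 T cells could give, but it cannot be told apart from fewer transcripts per cell. Tnfsf11, another such signal, was 6.9 and 7.25 CPM and did not pass.

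The residual Tox reads, 12.6 ± 2.43 CPM (n = 3), are counted over the whole gene, and transcripts of the recombined allele were not separated from those of cells with an intact allele.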
